A study of Homo sapiens with 4 samples.

How the data were processed

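Total RNA of cells labelled MCF-7, 36 hours after transfection with a control plasmid or a PD-L1 plasmid, was sequenced in 4 libraries, 2 per group. The authors deposited a table of TPM per gene, with a column for each library and a mean column for each group. Per the submitters' processing notes, fastp, HISAT, RSEM and the build GRCh38 were used, while versions, the annotation release, the strand setting and filters are not given in the sources used here. The table holds 59501 genes, 58884 with an Ensembl identifier and 617 assembled genes with no symbol. In 27 rows the symbol had turned into a date, so genes were matched to the annotation by Ensembl identifier. List members and named genes were found by symbol. TPM values are given to 2 decimals and each library sums to 1000000 within rounding, so a gene that takes a larger share lowers the others and the depth behind a value is unknown. An exact 0 can be a failed estimate, since genes used by every cell, such as the U4 RNA gene RNU4-2, are also listed at 0. Coordinates, gene type and the GC content of the longest transcript came from GENCODE 29 on the same build, which matched 58611 identifiers.

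Groups and replicate numbers came from the sample labels. The test, the gene lists and the rule for named genes were fixed before the data were examined. Genes with a mean of at least 1 TPM over the 4 libraries (14988 genes) were tested on log2(TPM + 1), with a pseudocount of 1, by limma (lmFit and eBayes with trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of single genes are from this model. Of 39 gene lists fixed, 36 had at least 5 tested members. They were tested with limma's camera with a preset correlation of 0.01 and adjusted over the lists, with CD274 left out since the plasmid sets it. The p-values of this test reflect the spread over genes more than that between the 2 libraries of a group. Where the correlation is estimated instead, camera rests on the 2 residual degrees of freedom. That version could hardly call any list, whatever the correlation. Fold changes are PD-L1 minus control on the log2(TPM + 1) scale and understate the change of low genes. With 2 libraries against 2, an exact permutation test of a single value cannot give a two-sided p below 0.333.

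The genes named are, by the rule, CD274, LAMTOR5, EP300, PDCD1LG2, JAK2, ESR1, PGR, GATA3, MKI67, MYC, CCND1 and CDKN1A in all cases, the genes with a symbol past the threshold, and up to 5 genes with a symbol per direction filled from the smallest p. The assembled gene MSTRG.18287 has no symbol and was named after its values were seen. From called lists the rule gives up to 4 members past the threshold over all genes, of which there were 0. The members named from called lists, and the copies of named genes, were therefore chosen after their values were seen.

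The steps were tested on simulated data: in 20 simulations of PD-L1 against control over 14988 genes, 200 of them changed, limma recovered 9.8% of genes changed by 0.5 on the log2 scale, 50.1% at 1, 79% at 2 and 89.7% at 4, and 4.59% of its calls were false. A list shifted by 0.15 was called in all 20, and 1 of 700 unshifted lists was called. The simulated genes varied independently, so this does not cover a trend shared by many genes.

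Alternatives were other pseudocounts, filters, scalings, thresholds and variance settings, the replicate number as a block, leaving out each library, and other list tests. A loess correction of each library for GC content and length (span 0.3), and a test of protein-coding genes only, were chosen after seeing the data. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.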

Results

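RNA was sequenced from cells that the labels name MCF-7, an established breast cancer line described as luminal and estrogen receptor positive. Many luminal genes were low in all 4 libraries, as given below, so the identity of the cells rests on the labels. The cells had been transfected for 36 hours with an empty expression plasmid (control) or with a plasmid that carries PD-L1, the immune checkpoint ligand encoded by CD274. Each group had 2 libraries, which the labels describe as biological replicates, and the series asks what PD-L1 overexpression does in breast cancer cells. Expression was given in TPM, the share of transcripts corrected for transcript length, for 59501 genes. TPM keeps no read depth, so the depth of the libraries is unknown and the precision rests on the spread between the 2 libraries of a group. The 2 control libraries had 14876 and 14865 genes at 1 TPM or more, and the 2 PD-L1 libraries had 14919 and 14879. The 10 most abundant genes held 9.71% and 10.0% of the total in the controls and 9.63% and 9.81% in the PD-L1 libraries.

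CD274 (ENSG00000120217, GRCh38 chromosome 9, 5450503 to 5470566, plus strand, protein coding) rose from 0.64 TPM in each control library to 52.05 and 42.61 TPM in the PD-L1 libraries. The log2 fold change on the log2(TPM + 1) scale was 4.87 (SE 0.131, n = 2 per group, limma adjusted p = 0.00437), a scale that understates the change of a gene this low in the controls. Values per gene do not separate plasmid transcripts from those of the chromosomal gene. Beside CD274, the test called RNA5SP216, a 5S ribosomal RNA pseudogene of 123 bases (chromosome 6, 125979812 to 125979934, minus strand, within the span of HINT3 on the opposite strand). RNA5SP216 was listed at 0 in both controls and at 50.9 and 52.7 TPM in the PD-L1 libraries (limma adjusted p = 0.00137), and short RNA genes of this kind often switched between 0 and 5 TPM or more within a group. Of 14988 genes tested, limma called 2 higher and 0 lower, while 1523 were higher and 613 lower at an unadjusted p under 0.05. This total of 2136 was 1401 after a correction for GC content and length. It was lower or higher depending on which library was left out. With any 1 of the 4 libraries left out, limma called 0 genes, and the adjusted p of CD274 lay between 0.132 and 0.218.

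**Figure D1:**
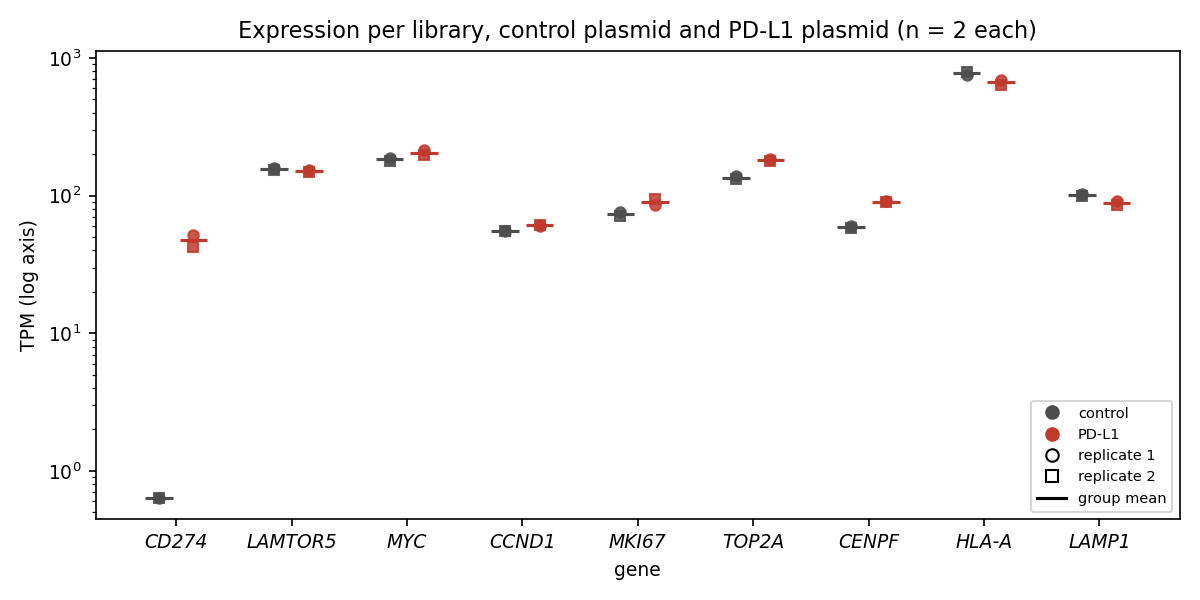
TPM on a log axis for 9 genes in each of the 4 libraries, with circles for replicate 1, squares for replicate 2 and a line at each group mean. CD274 lies at 0.64 TPM in both controls and at 52.05 and 42.61 TPM with the PD-L1 plasmid, and LAMTOR5 lies between 147 and 159 TPM in all 4.

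The partners and regulators that the study's title concerns showed no difference past the threshold. LAMTOR5, which encodes HBXIP, a subunit of the Ragulator complex on lysosomes, was at 156 ± 4.60 TPM (SD, n = 2) in controls and 150 ± 3.52 TPM with PD-L1, a log2 fold change of -0.06 (limma adjusted p = 0.642). The acetyltransferase gene EP300 was at 23.5 ± 1.64 and 25.8 ± 4.93 TPM (limma adjusted p = 0.742). JAK2, a neighbour of CD274 on chromosome 9, was at 2.59 ± 0.0283 and 3.37 ± 0.248 TPM (limma adjusted p = 0.463). PDCD1LG2, which encodes the other PD-1 ligand, was listed at 0 in 3 libraries and at 0.03 TPM in PD-L1 replicate 1. None of the lists of checkpoint ligands and the PD-L1 locus (13 members tested), HBXIP and its Ragulator partners (15) or acetylation writers and erasers (24) was called. Their adjusted p-values in limma's camera test were 0.633, 0.633 and 0.839. In these lists and others that were not called, 12 in all, the median, the mean and the test differed in sign, and in 0 of the 8 called lists.

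The lists of mitosis and DNA damage repair were higher with the PD-L1 plasmid. In the mitosis list, 33 of 40 members had a higher mean, 10 rose adjusted over the list alone and 0 over all genes tested, and the median log2 fold change was 0.08 (camera adjusted p = 0.000438, and adjusted p = 0.734 with an estimated correlation). CENPF, a kinetochore protein gene, rose from 59.1 ± 1.41 to 90.3 ± 1.09 TPM (SD, n = 2), with a limma adjusted p of 0.00486 over the list alone and 0.142 over all genes. TOP2A, which encodes DNA topoisomerase II alpha, rose over the list alone from 134 ± 4.70 to 182 ± 4.79 TPM, and the spindle motor gene KIF11 from 42.6 ± 2.18 to 57.2 ± 1.42 TPM. The proliferation marker MKI67 rose over the list alone from 73.5 ± 3.01 to 90.4 ± 6.36 TPM (limma adjusted p = 0.0426 over the list, 0.234 over all genes). The other 7 members had a lower mean, and 4 of them were lower in both PD-L1 libraries than in both controls. These were MYBL2 (160 ± 0.156 and 146 ± 6.94 TPM), FOXM1 (133 ± 0.445 and 123 ± 7.93), PLK1 (114 ± 0.580 and 107 ± 3.98) and AURKB (96.31 ± 6.45 and 89.85 ± 0.0707). None of these 4 passed the threshold, over the list alone or over all genes. In the DNA damage repair list, 25 of 30 members had a higher mean (median 0.18, camera adjusted p = 0.000438, and adjusted p = 0.734 with an estimated correlation), and FANCI and BRCA2, genes of crosslink repair and homologous recombination, rose adjusted over the list alone. FANCI went from 105 ± 3.48 to 135 ± 3.22 TPM and BRCA2 from 3.66 ± 0.0283 to 6.63 ± 0.283 TPM. The DNA replication list (24 of 42 members higher, camera adjusted p = 0.551) and the G1 cyclins and CDK inhibitors (9 of 16 higher, adjusted p = 0.935) were not called, nor were MYC (183 ± 6.08 and 204 ± 12.6 TPM), CCND1 (55.2 ± 0.297 and 60.9 ± 0.785 TPM) or CDKN1A (137 ± 6.51 and 126 ± 5.32 TPM) past the threshold.

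The list of ribosome biogenesis and MYC targets was also higher, with 26 of 33 members higher in the mean, 11 risen adjusted over the list alone and a median of 0.15 (camera adjusted p = 0.000555, and adjusted p = 0.734 with an estimated correlation). Without PD-L1 replicate 1 the median was 0.09. DDX21, an RNA helicase of ribosomal RNA processing, rose over the list alone from 166 ± 6.23 to 221 ± 8.66 TPM, and NOP58, a core protein of box C/D small nucleolar ribonucleoproteins, from 75.3 ± 1.03 to 104 ± 8.83 TPM. NPM1, the nucleolar chaperone nucleophosmin, rose over the list alone from 1489 ± 3.90 to 1768 ± 72.9 TPM. The cytosolic ribosomal protein genes were not called (32 of 77 higher, camera adjusted p = 0.231).

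The list of interferon gamma response and antigen presentation was lower, though only 15 of its 32 genes were tested. The GBP and CXCL genes, IDO1, CIITA and SOCS1 were not among those tested. The call therefore rests mostly on antigen presentation genes and says little of the interferon gamma response itself. Of its 15 tested members, 14 had a lower mean with the PD-L1 plasmid (median -0.16, camera adjusted p = 0.000913, and adjusted p = 0.734 with an estimated correlation). Adjusted over the list alone, 0 passed the test. HLA-A, a class I antigen-presenting molecule, was at 771 ± 26.3 TPM in controls and 665 ± 37.8 TPM with PD-L1. TAPBP, which loads peptides onto class I molecules, was at 44.5 ± 2.11 and 36.7 ± 0.750 TPM, and the immunoproteasome gene PSMB9 at 18.3 ± 1.17 and 14.1 ± 1.66 TPM. B2M changed little, at 3306 ± 28.2 and 3281 ± 13.3 TPM, as did HLA-E, at 52.9 ± 1.03 and 52.4 ± 4.09 TPM. IRF1 had a higher mean with PD-L1, at 9.135 ± 0.247 and 10.8 ± 0.332 TPM. The type I interferon list was not called (14 of 32 higher, camera adjusted p = 0.586), nor was the list of NF-kappaB targets (6 of 15 higher, adjusted p = 0.586).

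Lysosome and energy metabolism lists were lower. The autophagy and lysosome list had 23 of 29 members lower (median -0.08, camera adjusted p = 0.00214, and adjusted p = 0.734 with an estimated correlation), with LAMP1, a lysosomal membrane protein gene, at 101 ± 2.31 TPM in controls and 88.2 ± 3.46 TPM with PD-L1. Nuclear-encoded oxidative phosphorylation had 43 of 64 lower (median -0.04, camera adjusted p = 0.0146), mitochondrial-encoded genes 9 of 13 (median -0.03, 0.0284) and glycolysis 17 of 24 (median -0.06, 0.0300). With an estimated correlation, the adjusted p of each of these 3 lists was 0.734. The pyruvate kinase gene PKM was at 2015 ± 6.29 and 1823 ± 67.2 TPM, and MT-ND6, a mitochondrial-encoded complex I gene, at 2093 ± 6.82 and 1682 ± 181 TPM. MT-ND6 fell the most of the 13 mitochondrial-encoded genes, and 4 of the 13 had a higher mean. The share of total TPM held by these 13 genes overlapped between groups. It was 9.06% and 9.29% in controls and 8.82% and 9.29% with PD-L1. Within these 4 lists 0 members passed the test adjusted over the list alone. The glycolysis median was -0.016 without PD-L1 replicate 2 and -0.12 without PD-L1 replicate 1. The oxidative phosphorylation median was -0.0048 without PD-L1 replicate 2, -0.06 without control replicate 1 and -0.07 without PD-L1 replicate 1, and that of mitochondrial-encoded genes -0.04 without control replicate 1, -0.017 without control replicate 2 and -0.06 without PD-L1 replicate 2. The glycolysis list was not called without control replicate 1 (camera adjusted p = 0.108), control replicate 2 (0.206) or PD-L1 replicate 2 (0.227). Oxidative phosphorylation was not called without control replicate 2 (0.313) or PD-L1 replicate 2 (0.134), nor mitochondrial-encoded genes without control replicate 1 (0.0703), control replicate 2 (0.313) or PD-L1 replicate 1 (0.472).

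**Figure D2:**
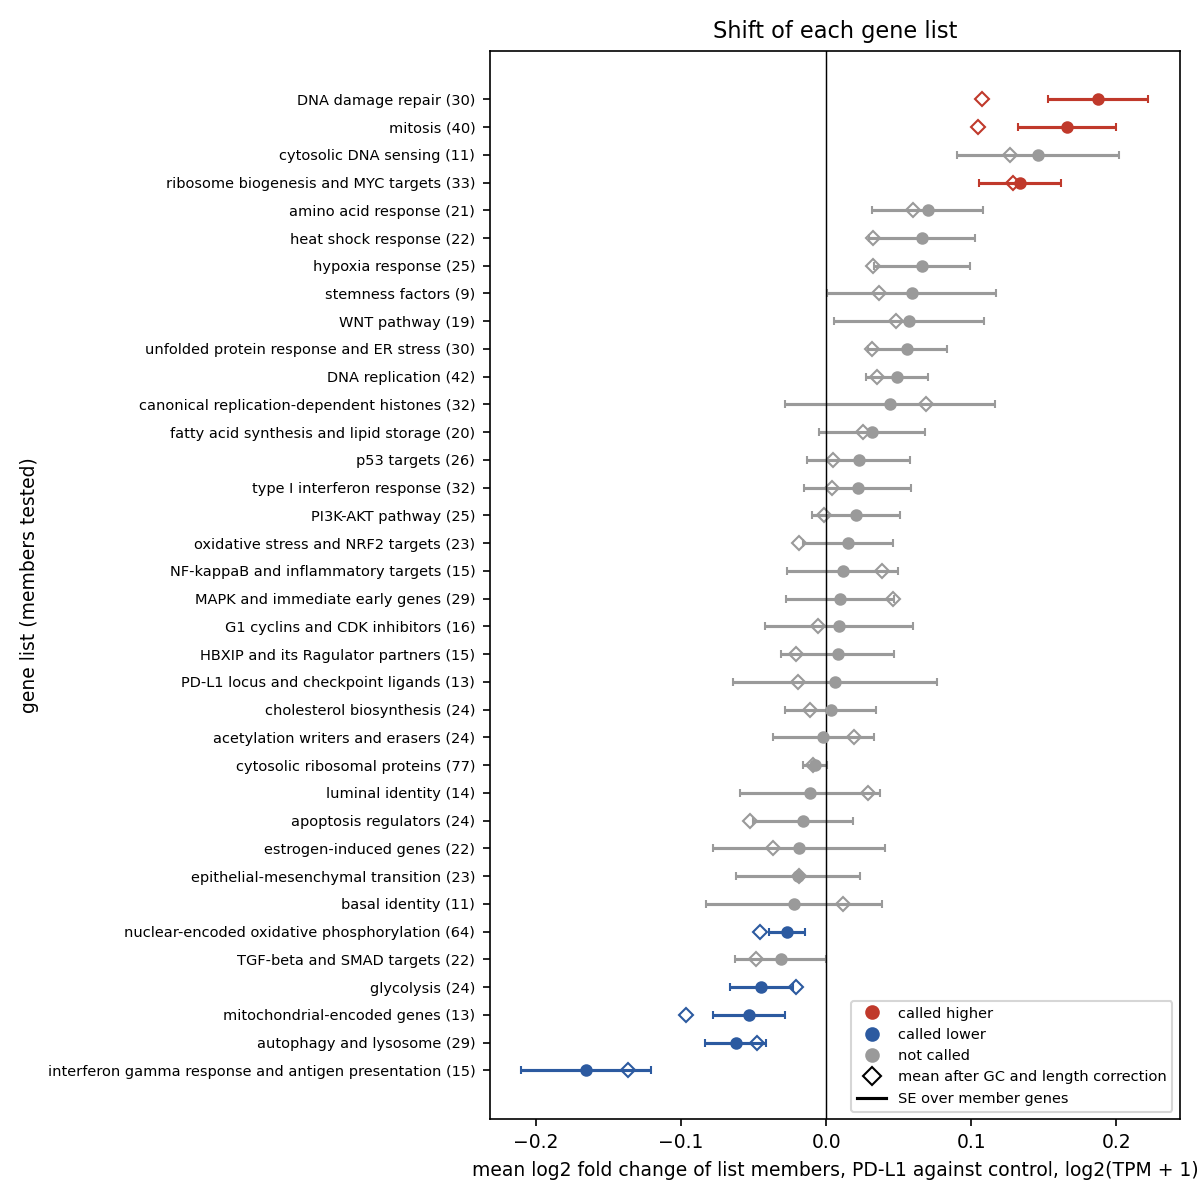
Mean log2 fold change of the members of each of the 36 gene lists tested, PD-L1 against control on the log2(TPM + 1) scale, with bars for the SE over member genes and open diamonds for the mean after a correction for GC content and length. The 3 lists called higher are red and the 5 called lower are blue, and the interferon gamma and antigen presentation list lies lowest, at -0.17.

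The libraries also differed in a way that followed the GC content of the genes. Across protein-coding genes, which are not independent replicates, the log2 fold change fell with GC content (Spearman's rho = -0.58). The fifth of these genes lowest in GC content had a median log2 fold change of 0.21 and the fifth highest in GC content a median of -0.09. Against a median GC content of 48.7% over all tested genes, the shift of 5 called lists ran with this trend. By list median, that of the other 3 ran against it. Ribosome biogenesis and MYC targets were higher at 50.9%, and oxidative phosphorylation and mitochondrial-encoded genes lower at 47.9% and 44.3%. The medians 50.9%, 47.9% and that of autophagy and lysosome (51.1%) say little of direction. Protein-coding genes at 45.8% to 52.0% had a median log2 fold change of 0.003. The ribosome biogenesis members of smallest p, DDX21, NOP58, HSPD1 and NPM1, rose at 41.1% to 44.2%, while MYC was higher at 53.9%. In oxidative phosphorylation NDUFA5 (35.0%) and NDUFB5 (39.8%) were higher and NDUFS6 (53.9%) and NDUFS3 (55.7%) lower. The trend within lists was not tested. PD-L1 replicate 2 lay apart from the other 3 libraries on the first principal component (37.9% of the variance), and its difference from PD-L1 replicate 1 also followed GC content (rho = -0.28), while that between the controls had a rho of 0.13. The Pearson correlation of log2 values across genes was 0.975 between the controls, 0.971 between the PD-L1 libraries and from 0.969 to 0.975 between groups. When each library's trend on GC content and length was removed, a correction chosen after seeing the data, 7 of the 8 lists were still called and glycolysis was not (camera adjusted p = 0.217). The correction moved the median of DNA damage repair from 0.18 to 0.08, that of glycolysis from -0.06 to -0.0044 and that of mitochondrial-encoded genes from -0.03 to -0.06. The risen genes CENPF, TOP2A, KIF11, MKI67, FANCI, BRCA2, DDX21, NOP58 and NPM1 all had a GC content below 48.7%, from 36.3% (BRCA2) to 48.3% (MKI67). Among lower genes, HLA-A (58.0%), TAPBP (57.6%), PKM (53.3%) and LAMP1 (51.2%) lay above 48.7%, and PSMB9 (46.9%) and MT-ND6 (42.7%) below. The TPM values given for these genes are not corrected for GC content.

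**Figure D3:**
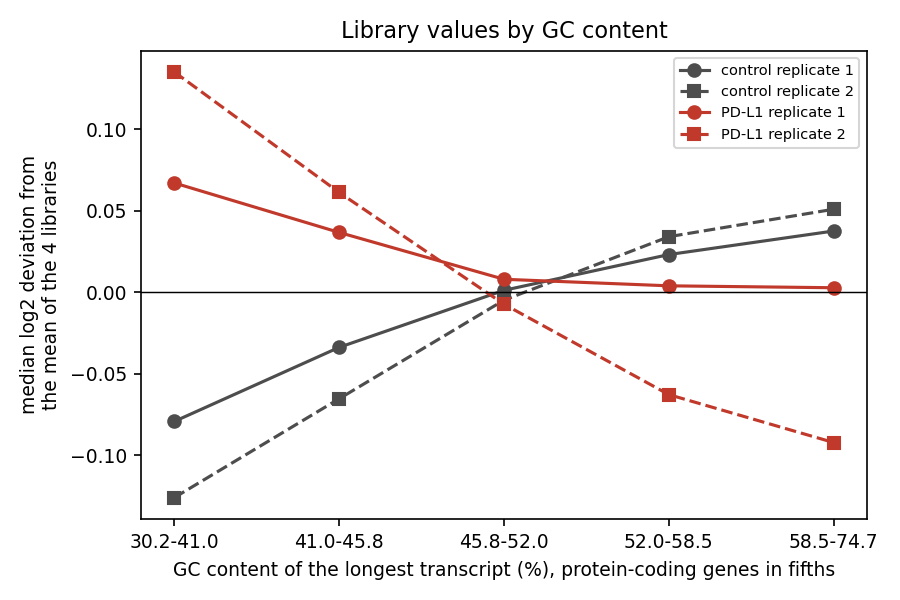
Median log2 deviation of each library from the mean of the 4 libraries, for protein-coding genes in 5 groups of equal size by GC content (percent of the longest transcript). In the group lowest in GC content the controls lie at -0.08 and -0.13 and the PD-L1 libraries at 0.07 and 0.14.

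The genes nearest to the threshold beside those called did not pass it over all genes. BOLA2 was at 7.99 and 6.93 TPM in controls and 26.02 and 25.13 TPM with PD-L1 (limma adjusted p = 0.0817). Its near-identical copy BOLA2B was at 386.6 and 392.33 TPM in controls and 372.96 and 342.71 TPM with PD-L1. The division of reads between them is uncertain. Their summed TPM overlapped between groups, at 394.59 and 399.26 in controls and 398.98 and 367.84 with PD-L1. MSTRG.18287, an assembled gene with no symbol, was at 100.97 and 107.08 TPM in controls and 40.05 and 34.96 TPM with PD-L1 (limma adjusted p = 0.0817), the smallest adjusted p among lower genes. AL161431.1, a long intergenic RNA (chromosome 13, 109269634 to 109278512), was at 166 ± 3.22 TPM in controls and 114 ± 1.14 TPM with PD-L1 (limma adjusted p = 0.142). The pseudogene SRP9P1 was at 91.0 ± 15.1 TPM in controls and 33.3 ± 0.537 TPM with PD-L1. Its parent gene SRP9, which shares sequence with it, was at 328.04 and 320.73 TPM in controls and 367.17 and 400.91 TPM with PD-L1. This division is uncertain too, and the summed TPM overlapped, at 429.76 and 401.08 in controls and 400.82 and 433.8 with PD-L1. The small nuclear RNA gene RNVU1-6 was at 11.34 and 10.59 TPM in controls and 26.96 and 31.03 TPM with PD-L1. Listed at 0 in both PD-L1 libraries were RNU4-2 (47.46 and 22.18 TPM in controls), RNU2-4P (4.25 and 4.17 TPM) and the pseudogene CU639417.3 (8.53 and 13.60 TPM).

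Markers of the luminal lineage were split between low and abundant genes, with either plasmid. The keratin genes KRT8 and KRT18, both on the luminal identity list, were at 1867 ± 50.6 and 1327 ± 5.64 TPM in controls and at 1615 ± 52.3 and 1237 ± 40.1 TPM with PD-L1. The estrogen receptor gene ESR1 was at 3.68 ± 0.247 TPM in controls and 3.98 ± 0.149 TPM with PD-L1 (limma adjusted p = 0.783), and GATA3, a luminal transcription factor gene, at 1.08 ± 0.417 and 1.08 ± 0.0212 TPM (adjusted p = 0.984). The progesterone receptor gene PGR was listed at 0 in all 4. Of 24 genes of the luminal identity list, 16 had a mean under 5 TPM, 10 of these had a mean under 1 TPM, and 4 were listed at 0 in every library. The list was not called among its 14 tested members (camera adjusted p = 0.211), nor were the estrogen-induced genes (22 tested, adjusted p = 0.342) or the basal identity genes (11 tested, adjusted p = 0.288). Markers of other cell types were too few for a test, with 3 of 21 immune cell genes, 4 of 17 fibroblast and endothelial genes and 4 of 25 markers of other laboratory lines above a mean of 1 TPM. The most abundant of each were CD68 at 12.4, COL1A1 at 52.1 and MAGEA1 at 33.1 TPM.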

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

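The alternatives with a GC and length correction or protein-coding genes alone were chosen after seeing the data, and the others before. The number of genes called was 2 (2 higher, 0 lower) and that of lists 8. A pseudocount of 0.1 gave 5 genes, 2 of them lower. A filter of at least 5 TPM, eBayes without trend, robust eBayes and a threshold of 0.1 each gave 4 genes, 1 of them lower. No filter gave 1 gene, which was higher, and 5 lists, and the adjusted p of CD274 was 0.0850 at a log2 fold change of 4.87, with more genes tested. With CD274 and mitochondrial genes removed, 1 gene was called, which was higher. Leaving out each library in turn gave 0 to 0 genes called, 0 to 0 of them higher, a log2 fold change of CD274 from 4.73 to 5.02 (adjusted p from 0.132 to 0.218) and 5 to 7 lists, the 5 without control replicate 2. These fits have fewer samples, and the lone library left in a group is assumed to vary like the other group. Quantile normalization and eBayes without trend gave 5 lists, camera with an estimated correlation 0 and fry, which does not compare a list with other genes, 1 (the WNT pathway). For the other changes the cause was not tested. Mitosis, DNA damage repair, ribosome biogenesis and MYC targets, interferon gamma response and antigen presentation, and autophagy and lysosome were called under 18 of 20 alternatives, all but the estimated correlation and fry. Robust eBayes, counted among the alternatives, does not enter the list test and could not change it. The 18 all kept the preset correlation of 0.01. The estimated correlation was 0.125 for mitosis and 0.107 for DNA damage repair. It was 0.0794 for ribosome biogenesis, 0.0063 for autophagy and lysosome and -0.019 for the interferon gamma list. The autophagy and interferon gamma values lie below the preset 0.01, yet these lists lost the call too. The size of the correlation therefore does not account for their loss. With 2 residual degrees of freedom the loss of all calls was close to fixed in advance and decides little. Oxidative phosphorylation was called under 13 of 20, mitochondrial-encoded genes under 11 of 19 and glycolysis under 10 of 20. No called result changed direction, though the median of mitochondrial-encoded genes was 0 with quantile normalization. Of single list results 681 stayed on their side of the threshold, 35 lost the call and 3 gained it, and of named gene results 1699 stayed, 4 lost it and 7 gained it, with direction judged for called results only. The scalings left the median log2 fold change of all genes between -0.01 and 0.02. With the replicate number as a block, 2 genes (2 higher, 0 lower) and 8 lists were called, and the deviations of same-numbered libraries had a correlation of -0.07, so the numbers were not treated as pairing the libraries. Count-based tests and filters listed as alternatives were not run, since TPM are not counts. The unknown depth limits what can be said of genes listed at 0.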

Other observations

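The tests of faster cycling, of low estrogen signalling and of the GC trend in the 4 lower lists other than glycolysis, the gene families grouped by symbol and the genes named in these paragraphs were chosen only after the results were seen. Some members of lists that were not called passed the test adjusted over their own list alone, while other members of the same lists went the other way, with 8 of 22 lower in the heat shock list 14 of 23 lower in the list of oxidative stress and NRF2 targets and 5 of 11 higher in the basal identity list. HSP90AA1, a cytosolic chaperone gene, rose over the heat shock list from 685 ± 24.5 to 876 ± 30.6 TPM (SD, n = 2, limma adjusted p = 0.0190 over the list and 0.171 over all genes), and HSP90B1, its counterpart of the endoplasmic reticulum, rose over the unfolded protein response list from 616.06 and 586.34 to 754.42 and 788.87 TPM. NFE2L2, which encodes the oxidative stress regulator NRF2, rose over its list from 50.7 ± 0.0212 to 67.3 ± 2.02 TPM, and the cystine transporter gene SLC7A11 from 90.4 ± 4.45 to 117 ± 2.79 TPM. The hypoxia factor gene HIF1A rose over its list from 77.5 ± 1.11 to 99.0 ± 0.948 TPM. KRT17 and TRIM29 fell over the basal identity list, KRT17 from 76.2 ± 1.77 to 61.5 ± 2.48 TPM and TRIM29 from 131 ± 0.665 to 108 ± 7.09 TPM. The median of that list went from -0.06 to 0.01 with the GC and length correction. All these single genes moved in the direction of the GC trend, and their TPM values are not corrected for it. SLC7A11 (35.4%), HIF1A (36.4%), HSP90B1 (41.2%), HSP90AA1 (45.2%) and NFE2L2 (45.6%) rose below the median GC content of 48.7%. KRT17 (58.1%) and TRIM29 (58.6%) fell above it. Of 79 gene families with at least 15 tested members, camera called 1, the centrosomal CEP genes, with 25 of 34 higher and a median of 0.16 (adjusted p = 0.0387). The CEP call was not kept after the GC and length correction (adjusted p = 0.215) or with an estimated correlation (adjusted p = 0.876).

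Many luminal genes that the label MCF-7 would lead a reader to look for were low in all 4 libraries, while others were not: TFF1, TFF3 and PGR were listed at 0 in each library, FOXA1 had a mean of 2.93 TPM, and the epithelial genes CDH1, EPCAM and KRT19 had means of 0.938, 2.02 and 0.455 TPM. KRT8 was at 1741 TPM, KRT18 at 1282, XBP1 at 117, MUC1 at 40.7 and ELF3 at 26.1 TPM, with VIM, a mesenchymal intermediate filament gene, at 450 TPM, KRT7 at 423 TPM and CDKN2A, a gene that published genotypes of MCF-7 describe as deleted, at 453 to 493 TPM. Low estrogen signalling alone stays open, since the 8 lineage genes tested for it (median 0.696 TPM) were chosen after their low values had been seen and leave out abundant ones. A candidate explanation is that the cells lacked part of the luminal programme, as another line or a changed subline. The median of 12 further luminal or epithelial genes, fixed before their values were seen, was 1.72 TPM, but the set was split. The 6 under 1 TPM were RAB25, ESRP1, BCAS1, GRHL2, NPY1R and SPINT1, at 0, 0.01, 0.02, 0.025, 0.175 and 0.32 TPM. TRPS1 was at 3.11 TPM, and ST14, STARD10, CELSR2, PREX1 and SLC9A3R1 were at 5.62, 8.52, 11.2, 16.1 and 47.6 TPM. The CDKN2A level goes against a changed subline if that deletion holds for the cells used, which was not checked here, and both groups share the feature.

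For the 8 shifted lists, found beside a log2 fold change that fell with GC content, a possible cause is a trend with GC content and length. This trend is argued against as the whole cause for the 3 higher lists, since 3 of 3 were still called after the correction. The mean of the mitosis list went from 0.17 to 0.10 and that of DNA damage repair from 0.19 to 0.11. For the 5 lower lists the trend stays open, since 4 of the 5 were still called. The 4 lower lists other than glycolysis were set apart after glycolysis had lost its call. That 4 of these 4 were still called was therefore fixed in advance and decides nothing. The means of oxidative phosphorylation and mitochondrial-encoded genes went from -0.03 to -0.05 and from -0.05 to -0.10. That of interferon gamma response and antigen presentation went from -0.17 to -0.14. The glycolysis mean went from -0.04 (SD over genes 0.11) to -0.02 (SD 0.07), the smaller shift ending its call. A few genes taking more of the total was not seen among the 10 most abundant genes. Their share was 9.71% and 10.0% in controls and 9.63% and 9.81% with PD-L1. The lower PD-L1 library minus the higher control was -0.379 percentage points. That difference is negative whenever the groups overlap, so with 2 libraries per group it says little, and less abundant genes were not examined. The GC trend itself may come from library preparation or sequencing. Its slope in long non-coding genes was 0.587 times that in protein-coding genes, within the range predicted for this cause. The rank correlation was weaker there, at -0.18 against -0.58. A slope in both kinds of gene does not separate a technical from a biological trend, so the cause is not settled. The PD-L1 plasmid stays open, as 4 of 4 pairs of a control and a PD-L1 library had a negative rank correlation with GC content. These pairs share the same 4 libraries and are not independent, and the 2 PD-L1 libraries differed from each other with a rho of -0.28. The batch of preparation is not known. Faster cell cycling also stays open, since the DNA replication list was neither called higher nor lower (adjusted p = 0.551), and of the 3 splits of the 4 libraries 1, the real one, gave as many as 8 lists against 0 for the highest other, with too few splits for a share under 0.05.

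Short RNA genes were frequent among the largest differences, including RNA5SP216. Of 145 tested genes under 200 bases, 97 (66.9%) were at 0 in 1 library and at 5 TPM or more in the other library of the same group, against 79 of 14843 longer genes (0.532%), a ratio of 126. Unstable TPM of very short genes may therefore account for such differences between groups, and no biological explanation was tested. The other splits of the libraries called 3 and 5 genes, against 2 for the real split, among them the short RNA genes RNVU1-4, SNORD22 and SCARNA4.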
